A study of Mus musculus with 4 samples.

How the data were processed

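Tregs from mouse lymph nodes were profiled with droplet-based single-cell RNA sequencing from the 5' end of transcripts, with hashtag antibodies to tell the mice of a pool apart. The design text gives 4 mice per genotype and 2 pools. The 4 libraries were grouped by kind (RNA or hashtag) and by pool number. Every library mixes genotypes, so no library was assigned to control or knockout. Cells were sorted as viable cells positive for TCRb, CD4, GFP and tdTomato, per the labels' protocols.

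The submitters' processing notes name Cell Ranger 7.1 and the build mm10. The names of the lists call them filtered. The settings of the filter that called cells and the gene annotation are not given in the sources used here. The 5 files analysed were text: a list of cell barcodes and a list of features for each pool, and the table of hashtag sequences. They hold no measured values. The pool of each list was taken from the name the authors gave it. As deposited, each line of a barcode list is a barcode of 16 bases with the suffix 1, and each line of a feature list gives an identifier, a name and the kind of feature. Count matrices were not analysed here. The test planned for them was edgeR's quasi-likelihood test on counts summed per mouse, but it was not run, and no cell was assigned to a mouse, clustered or screened for doublets.

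Barcodes were counted per list, with exact Poisson intervals at the 95% level, which cover counting error only. Identical barcodes in both lists were counted and set against independent draws from 737280 barcodes with an exact hypergeometric test at a threshold of 0.05. That list size, fixed before the data were examined, equals the product of the 480 first parts and 1536 last parts seen in the lists. The place to divide the barcode, after base 7, was the only 1 of 15 at which the product of distinct first and last parts came to that size. Shuffles of last against first parts within each list, which keep the frequency of each part, were drawn 100000 times. A shuffled list may hold a barcode more than once, unlike the real lists, and shared barcodes were counted with such repeats. The spread of the shuffled counts was not adjusted for this. A first set of 10000 shuffles had left the outcome within its sampling error of the 2.5% limit. The test was checked on 200 simulated pairs of lists of the same sizes, with no planted overlap and again with 100 planted shared barcodes. It gave p under 0.05 in 5.0% of the first and 99.5% of the second. The simulated lists were drawn evenly, as the test assumes, so this checks the computation and not uneven use of whole barcodes. The observed excess was smaller (48.2), and no overlap of that size was simulated. Alternatives were a barcode list of 6794880, 1 mismatch allowed, the suffix removed, distinct barcodes in place of lines, and symbols matched in any case.

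Features were matched by identifier to GENCODE M21, and 32158 of 32285 genes (99.6%) had an entry. The annotation supplied here is not stated to be the one the authors used, so gene classes and coordinates describe M21. The 8 gene lists were targets (Gsk3a, Gsk3b), Treg identity (such as Foxp3, Il2ra, Ctla4 and Ikzf2), resting or central Treg (Ccr7, Klf2), effector Treg (Icos, Klrg1, Prdm1), Wnt and beta-catenin (Ctnnb1, Axin2, Lef1), proliferation (Mki67, Top2a), glycolysis (Slc2a1, Hk2, Ldha) and apoptosis (Bcl2, Bax, Fas). Markers of 8 cell types were listed as well. The rule for named genes was to name the targets, Foxp3 and any reporter feature where no expression test could run. Aldoa, Bcl2, Lef1, Tcf7, Crem, Creb1 and the genes overlapping the targets and Foxp3 fall outside it and were chosen after the lists were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.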

Results

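Regulatory T cells (Tregs) are the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The design sets Tregs that lost both Gsk3a and Gsk3b after tamoxifen against Tregs of control mice. Gsk3a and Gsk3b encode the alpha and beta forms of glycogen synthase kinase-3, a kinase that, among other roles, marks beta-catenin for degradation in Wnt signalling. By the series title, the question is whether the kinase is needed for Treg development and maintenance. Lymph node Tregs were sorted 14 days after tamoxifen from 4 control and 4 knockout mice. Recombined cells carried the red fluorescent reporter tdTomato. The cells of each mouse were tagged with a hashtag, an antibody that carries a DNA barcode, and mixed into 2 pools of 2 control and 2 knockout mice. Each pool gave 1 RNA library and 1 hashtag library, for 4 libraries in all.

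The material analysed held cell barcodes, feature names and hashtag sequences, and no read or UMI count. No level of Gsk3a, Gsk3b, Foxp3 or any other gene was therefore measured here in control or knockout cells. The comparison of knockout with control Tregs was not analysed here, and neither were the shares of Treg states or the share of cells per mouse. The depth per cell is unknown. What follows describes which genes and hashtags could be counted, how many cell barcodes each pool listed, and how the lists of the pools compare.

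Both genes targeted in the knockout were features of the reference in both pools. The exons deleted are not given in the sources used here, so whether counts from the 5' end would show the loss is not known. Gsk3a (ENSMUSG00000057177) lies on the minus strand of chromosome 7, from 25228258 to 25237851. Its 3 annotated transcripts have at most 11 exons. Gsk3b (ENSMUSG00000022812) lies on the plus strand of chromosome 16, from 38089001 to 38246084, and its 5 annotated transcripts have at most 12 exons. Foxp3 (ENSMUSG00000039521), the gene whose locus drives the tamoxifen-dependent recombinase, lies on the plus strand of chromosome X, from 7573644 to 7595245. It has 10 annotated transcripts of at most 14 exons. Coordinates are those of GENCODE release M21 on GRCm38, the assembly also called mm10, and each span covers the exons and introns of the whole gene. No other listed gene overlapped Gsk3b. Gsk3a overlapped 9130221H12Rik on the opposite strand. Foxp3 overlapped Flicr on its own strand, and Ppp1r3f and Ccdc22 on the opposite strand. Reads from the shared stretch of Foxp3 and Flicr cannot be assigned by strand.

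The gene lists fixed before the data were examined were covered in full. All 108 distinct genes of the 16 lists were named among the features. The reference names 32285 genes, so full coverage was likely beforehand, and it says nothing of expression in these cells. These included 15 of 15 Treg identity genes, 10 of 10 genes of resting or central Tregs and 16 of 16 genes of effector Tregs. The lists for Wnt and beta-catenin signalling (11 of 11), proliferation (10 of 10), glycolysis (13 of 13) and apoptosis (9 of 9) were also complete. Markers of Tregs, conventional CD4 T cells, CD8 T cells, B cells, myeloid cells, dendritic cells, NK cells and erythroid cells were all named too. Being named does not show that such transcripts or cells were detected. Bcl2, which blocks apoptosis, and Lef1 and Tcf7, partners of beta-catenin, each stood in 2 of the gene lists. Aldoa, a glycolytic aldolase, was the only member whose symbol named more than 1 feature. Its features ENSMUSG00000030695 (126795234 to 126800751) and ENSMUSG00000114515 (126800790 to 126809108) are neighbouring genes on the minus strand of chromosome 7.

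The reporters and the recombinase were not features of their own. Of 32289 features, 32285 were genes and 4 were hashtags, and the feature lists of the pools were identical. In all, 16 names held one of the strings tdTomato, GFP, Cre or ERT2, and each of the 16 was a mouse gene with an Ensembl identifier, such as Crem and Creb1. Transcripts of tdTomato, eGFP or the recombinase would thus have no counts of their own under these features. Among the 32158 genes found by identifier in GENCODE M21, 21625 were protein-coding, 427 were immunoglobulin segments and 270 were T cell receptor segments. A further 5605 were long intergenic noncoding RNA genes and 2955 were antisense genes. The features included 13 mitochondrially encoded genes, and 38 symbols named more than 1 gene.

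The 4 hashtags had 4 distinct sequences of 15 bases. These are synthetic antibody barcodes with no genomic position. HTO1 was ACCCACCAGTAAGAC and HTO2 was GGTCGAGAGCATTCA, and the labels give hashtags 1 and 2 to control mice. HTO3 was CTTGCCGCATGTCAT and HTO4 was AAAGCATTCTTCACG, and the labels give hashtags 3 and 4 to knockout mice. Each was read in R2 after 10 leading bases. The labels print 1 catalogue number for both hashtags 3 and 4, while the sequences of HTO3 and HTO4 differed at 12 of 15 bases. Over the 6 pairs of hashtags, the number of differing bases ranged from 11 to 13.

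Pool 1 listed 19725 cell barcodes, with an exact Poisson 95% interval from 19451 to 20002. Pool 2 listed 21857 cell barcodes, with an interval from 21568 to 22149. Pool 2 thus had 1.11 times as many as pool 1, and the intervals, which cover counting error only, did not overlap. Each pool is a single mixture of both genotypes, so this difference has no replicate check and says nothing of genotype. The protocol states that about 10000 cells were loaded for each batch. If a batch is a pool, the lists held 1.97 barcodes per stated cell in pool 1 and 2.19 in pool 2. Whether the stated number is a target or applies to a smaller unit than a pool is not known.

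**Figure D1:**
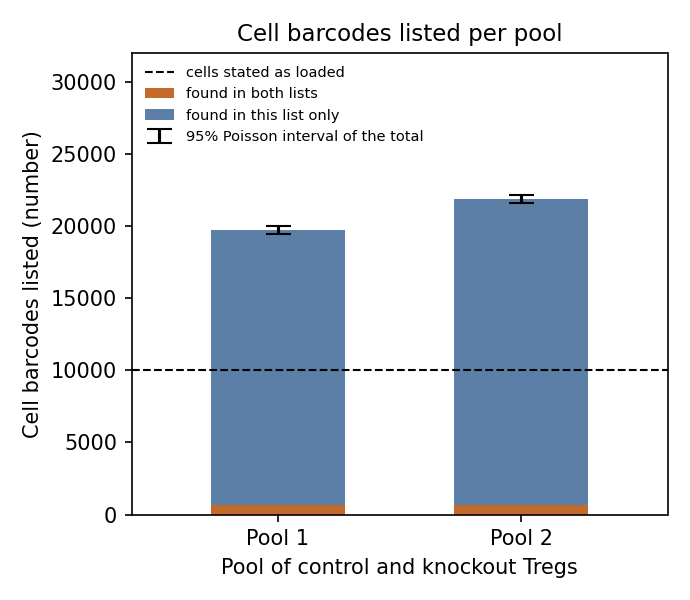
Number of cell barcodes listed for each pool (y axis), divided into those found in both lists and those found in 1 list only; black bars are 95% Poisson intervals of the totals and the dashed line is the load stated per batch. Pool 1 (19725) and pool 2 (21857) both lie above the 10000 cells stated as loaded.

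The barcode lists of the pools were compared to see whether they shared more barcodes than independent draws from the same barcode list would. This compares barcode sequences and cannot show whether any cell was common to both pools. No barcode was repeated within a list. In all, 633 barcodes stood in both lists, which is 3.21% of pool 1 and 2.90% of pool 2. Barcodes were 16 bases long, and their first 7 bases took 480 forms and their last 9 bases 1536 forms over both pools. With all combinations of these parts equally likely, 585 shared barcodes would be expected. The observed count was 1.08 times that number (two-sided exact hypergeometric test, p = 0.044). The test compares 2 lists, not the genotypes.

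**Figure D2:**
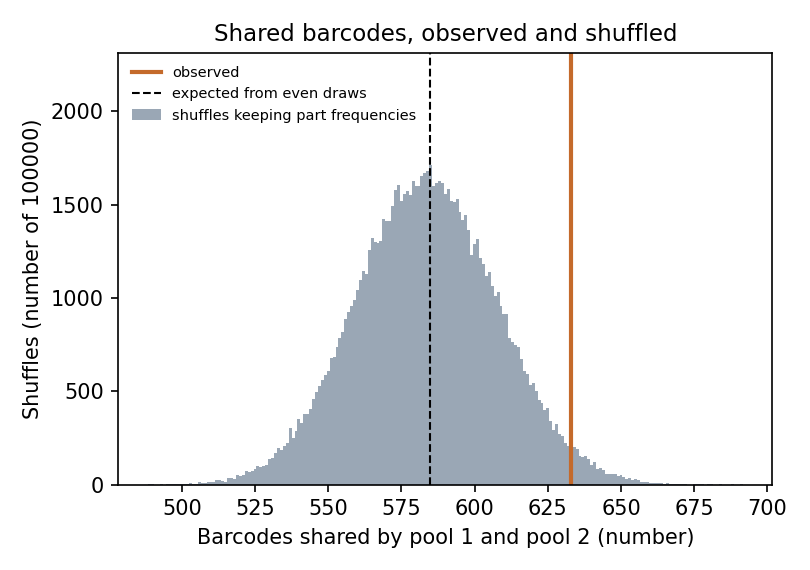
Number of barcodes shared by the pools (x axis) in 100000 shuffles of last against first barcode parts within each pool (bars; y axis, number of shuffles). The solid line marks the observed 633, in the upper tail of the shuffled counts, and the dashed line the 585 expected from even draws.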

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

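The number of shared barcodes stayed above the number expected, with p under 0.05, under each alternative tried. Only the alternative with the frequencies of the barcode parts could have lowered the ratio. The others could only keep the count, add to it or lower the expected number. Allowing 1 mismatch left the count at 633 and the ratio at 1.08, since it added no shared barcode. Within each list, 0 barcodes lay 1 mismatch from another, so this alternative had little room to add any and is not a separate check. Removing the suffix changed nothing, since each list has 1 suffix. The frequencies of the barcode parts, an alternative chosen after seeing the data, gave a ratio of 1.08. The larger barcode list gave a ratio of 9.98, but the parts seen, 480 first and 1536 last, allow far fewer barcodes than that list holds. With p = 0.044 in the planned exact test and 0.046 in the permutation test with the part frequencies (two-sided), the result lies close to the threshold of 0.05. Counting distinct barcodes left 19725 and 21857, and matching symbols in any case left 108 genes. The alternatives planned for expression (other normalization and filter, no pool term, mice left out in turn and stricter hashtag calls) were not run, because no counts were analysed. No paired analysis was possible because no counts, and so no value per mouse, were analysed. The lists limit what can be said to the number of barcodes: they give neither depth nor cell quality. The filter that called cells may have used either, and so affected which barcodes are listed.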

Other observations

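The tests of repeated barcodes and of barcodes listed for both pools were chosen after the counts per list had been seen; the limit for the test of barcode parts was set before its result. If the stated load is per pool, both pools listed about 2 barcodes for each cell loaded, although a droplet run commonly recovers fewer cells than are loaded. Repeated entries do not account for this, since the shorter list held 19725 distinct barcodes, against a stated 10000 cells. Nor do barcodes that stand in both lists, because 19092 of the shorter list were absent from the other. It stays open whether the stated number is a target or applies to something smaller than a pool, whether more cells were loaded, or whether droplets without a cell were called. The lists hold no UMI or hashtag counts to separate these, and no biological explanation was tested. Hashtag counts per barcode, with the share of barcodes positive for more than 1 hashtag, would be the first values to look at.

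The 633 barcodes common to both pools exceeded the 585 expected by 48.2. Uneven use of barcode parts was tested as a candidate explanation: shuffles that kept the frequency of every part shared 584 barcodes on average (SD 24.1 over shuffles), and 2.31% of them shared as many as observed, under the 2.5% limit set beforehand. The average was no higher than the 585 of even draws, so part use did not raise the expected count. The 2.31% therefore mostly repeats the upper tail of the exact hypergeometric test (p = 0.022) and is not separate evidence. The parts were used about as evenly as counting error allows. The variance of barcodes per first part was 1.06 times the mean in pool 1 and 0.93 times in pool 2, and for last parts 0.98 and 0.99 times (chi-square tests of even use, p from 0.18 to 0.87, 4 tests, unadjusted). Across parts, which are not replicates, the uses in both pools had a Pearson r of -0.0039 for first and -0.027 for last parts. A chance excess (exact hypergeometric p = 0.044), uneven use of whole barcodes and some barcodes carried between pools stay open; UMI counts of the shared barcodes in both pools would bear on the last. No biological explanation was tested.

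The number of combinations of barcode parts depends on where the barcode is divided, and the division after base 7 was taken because its product equals the list size assumed beforehand. At that division, the forms of the first 7 bases were 480 in each pool. The last 9 bases took 1535 forms in pool 1 and 1536 in pool 2, and the lists together held 5.55% of the combinations of these parts.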
